A study of Mus musculus with 6 samples.

How the data were processed

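RNA was sequenced from the suprachiasmatic nucleus (SCN), the hypothalamic site of the central circadian clock, of female C57BL/6 mice killed in darkness between zeitgeber time (ZT, hours after lights on) 12 and 14. The nucleus was punched from frozen coronal brain sections with a needle. Per the labels, each sample was a pool of RNA from 2 SCN, with 3 samples per genotype. The titles mark 3 libraries V (replicates 2, 3 and 4) and 3 libraries r1r2V (replicates 1, 4 and 5). The r1r2V libraries were read as the knockout of Nr1d1 and Nr1d2, which encode REV-ERBα and REV-ERBβ, in GABAergic neurons, and the V libraries as the control. The labels do not say whether the 2 SCN of a pool came from different animals or whether pools were independent, so p-values measure the spread between these samples.

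Per the file headers, the deposited tables give an expected count and an FPKM for each gene of each library. Expected counts are estimated read numbers that need not be whole, and 9.9% of the values deposited by the authors were not. The authors' FPKM values are fragments scaled by transcript length and by the mapped fragments of the library, per the file headers. Per the submitters' processing notes, the tools included HISAT2 2.0.4, StringTie 1.0.4, Cufflinks 2.2.1, GATK, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2, with the mouse build mm10. The role of each tool, the filters and whether the library kit kept strand are not given in the sources used here. The smallest FPKM listed was 0.01 in every library, and a gene that a table did not list was treated as 0 in that library. In all, 17645 genes were listed in at least 1 library and 15460 in all 6. The tables hold RefSeq mRNA features, and none of the 13 mitochondrially encoded mRNAs was among them.

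Total expected counts per library ran from 15729603 to 17780928. A count of 0 was taken to allow up to 3 counts, a floor that covers counting error only. Intervals of odds ratios are those of Fisher's exact test and treat genes as independent. Expected counts were rounded to whole numbers, and genes were kept by the default filter of edgeR 4.0.16 in R 4.3.3 (filterByExpr, minimum count 10), which left 14438 genes. Libraries were scaled by the trimmed mean of M-values. The groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are r1r2V minus V, and CPM values use the scaled library sizes. On counts simulated from these libraries for the same comparison, over 14438 genes, the test recovered 2% of genes changed 1.2-fold, 52% of those changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold. The changed genes were drawn from those with a mean of at least 1 CPM, 50 for each fold, so recovery below 1 CPM was not measured. Of the test's calls on the simulated counts, 5.4% were genes left unchanged. The simulation gave both groups the same spread for each gene, whereas the r1r2V libraries differed more among themselves than the V libraries. Recovery and wrong calls at unequal spread were not measured.

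The comparison, the 23 gene lists, the rule for named genes and the alternatives were set before the data were examined, apart from those stated to be later. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with adjustment over the 22 lists that had measured members, and again with an estimated correlation and with fry. Annotation terms in the files with 10 to 500 tested genes were tested for over-representation among the called genes with the hypergeometric test. The text names Nr1d1 and Nr1d2, and, in each direction, the 10 called genes with the largest change, a mean of at least 1 CPM, a symbol and groups that did not overlap. It also names up to 4 called members of each list and of each passing annotation term, and 17 clock, SCN and GABA genes whatever their p. Other genes named were chosen after their values were seen. A few genes that the rule or the lists take are not reported here.

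Gene positions are those of the RefSeq annotation of GRCm38, the assembly that mm10 names, and 17622 of the listed genes were placed. Strands are those of the GENCODE annotation. Near-identical copies were searched with BLAST+ 2.17.0 among the transcripts of 17487 genes (99.1%), at 95% identity or more over at least 0.5 of the shorter transcript, and 527 genes had one. Reads shared between such copies are divided by the estimation of expected counts, so values of single copies are uncertain. Gene totals cover all exons, and which exons were removed is not given in the sources used here, so the totals cannot show the deletion itself. Pairs of libraries of one group differed by more than sampling noise, so each library was counted as 1 sample. The chi-square per degree of freedom ran from 3.85 to 5.58 between V libraries and from 11.65 to 13.5 between r1r2V libraries.

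Alternatives were DESeq2 1.42.0 and limma-voom on the same counts, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other scalings, no filter, a filter of 1 CPM in 3 libraries, other thresholds, and leaving out each library in turn. Summing near-identical copies, and leaving chromosomes 2, 11 and 14 out of the counts, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.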

Results

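The data were gene-level RNA-seq values of SCN punches taken at ZT 12 to 14, from 3 libraries labelled V and 3 labelled r1r2V. Each library was a pool of RNA from 2 SCN, and total expected counts were 17780928, 17624211 and 15729603 in the V libraries and 17040698, 17566335 and 17355842 in the r1r2V libraries. The one comparison the design gives asks which transcripts differ when Nr1d1 and Nr1d2, genes of the clock's REV-ERB repressors, are deleted in GABAergic neurons.

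Nr1d1, one of the targeted genes, was 2.84-fold higher in the libraries labelled r1r2V than in those labelled V. Its level was 58.8 ± 3.27 CPM (SD, n = 3) in V and 167 ± 25.7 CPM (SD, n = 3) in r1r2V, a log2 fold change of 1.5 with a standard error of 0.106 and an adjusted p of 8.24e-05. All 3 r1r2V libraries (196, 157 and 147 CPM) lay above all 3 V libraries (56.7, 62.5 and 57.0 CPM). Nr1d2, the other targeted gene, had 175 ± 6.01 CPM (SD, n = 3) in V and 242 ± 28.6 CPM (SD, n = 3) in r1r2V, a log2 fold change of 0.47 that did not pass (adjusted p = 0.0553). Neither gene was lower in the libraries read as the knockout, so the direction of every comparison rests on the sample titles and not on the targeted transcripts. Nr1d1 (gene 217166) lies on chromosome 11 from 98767932 to 98775377 on the minus strand, and Nr1d2 (gene 353187) on chromosome 14 from 18204056 to 18239106, also on the minus strand (GRCm38). The end of Nr1d1 overlaps Thra, the gene of a thyroid hormone receptor on the other strand, by 1075 bp. Strand use in counting was not given, so reads of Nr1d1 and Thra cannot be told apart there. Thra fell from 627 ± 29.6 to 413 ± 40.0 CPM (SD, n = 3 each; log2 fold change -0.60, adjusted p = 0.00773). Nr1d2 passed with DESeq2 (adjusted p = 3.29e-05), without a filter (0.0267), and without r1r2V replicate 4 (0.0449) or 5 (0.0311), and its adjusted p over all alternatives ran from 3.29e-05 to 0.373.

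**Figure D1:**
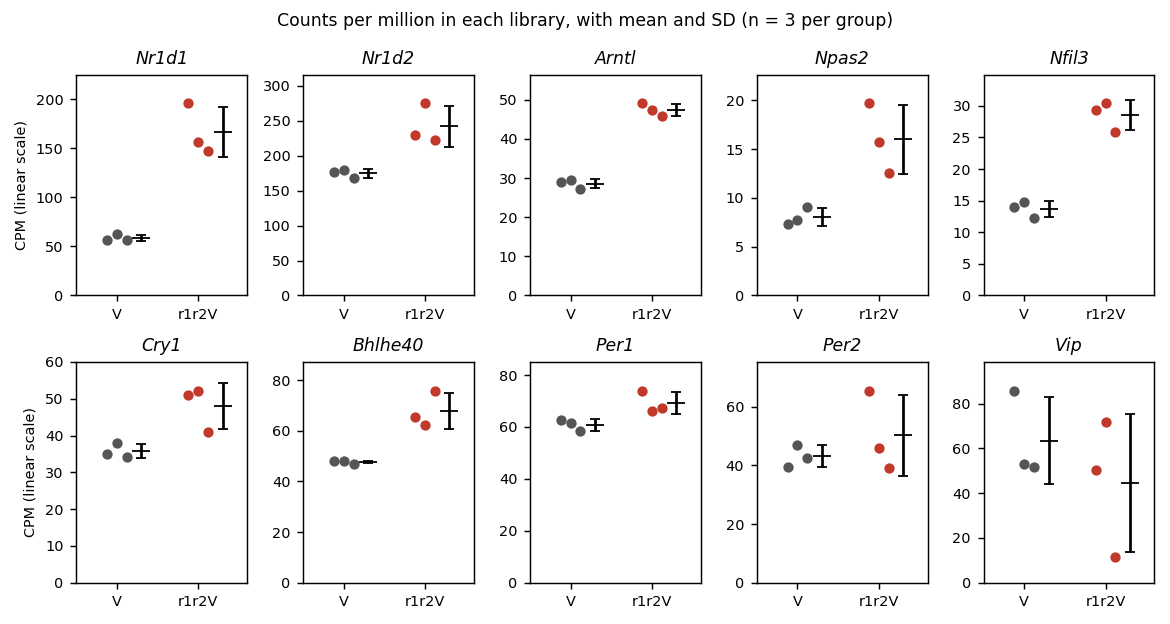
CPM on a linear axis for 10 genes in the V libraries (grey points) and the r1r2V libraries (red points), with the mean and SD of each group (bar and whiskers, n = 3). Nr1d1, Nr1d2, Arntl, Npas2, Nfil3, Cry1, Bhlhe40 and Per1 have every r1r2V library above every V library, while the groups overlap for Per2 and for Vip, which has 11.4 CPM in r1r2V replicate 5.

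Among clock genes with REV-ERB response elements, 3 of 6 rose in the r1r2V libraries. Nfil3, which encodes a D-box repressor, rose 2.08-fold, from 13.7 ± 1.25 to 28.5 ± 2.38 CPM (SD, n = 3 each; log2 fold change 1.06, adjusted p = 0.000881). Arntl, which encodes the clock activator BMAL1, rose 1.66-fold, from 28.6 ± 1.19 to 47.4 ± 1.61 CPM (SD, n = 3 each; adjusted p = 0.000914). Npas2, a partner of BMAL1, rose 1.99-fold, from 8.06 ± 0.903 to 16 ± 3.55 CPM (SD, n = 3 each; adjusted p = 0.0359). In the list of 6 clock genes with REV-ERB response elements, these 3 rose, 0 fell and 3 did not pass. Adjusted over the list alone, 4 rose, the fourth being Cry1, which encodes a clock repressor (log2 fold change 0.43, adjusted p over all genes 0.186). Clock had a log2 fold change of 0.10. The list passed as a set (camera, median log2 fold change 0.58, adjusted p = 7.64e-17), with 5 of 6 members positive, but not when the correlation was estimated (adjusted p = 0.14 with an estimated correlation). The calls of Nfil3 and Arntl held when any one library was left out, with adjusted p up to 0.0109 and 0.0136. The call of Npas2 ended without any 1 of the libraries except r1r2V replicate 5, with adjusted p from 0.00857 to 0.254 over the 6 fits, and it was lost with limma-voom and on FPKM values.

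Of 10 clock genes driven by E-boxes or D-boxes, 1 rose, 0 fell and 9 did not pass. Bhlhe40, which encodes a repressor of E-box transcription, rose 1.42-fold, from 47.7 ± 0.560 to 67.8 ± 7.03 CPM (SD, n = 3 each; adjusted p = 0.0318), a call that ended without any 1 of the V libraries (adjusted p up to 0.221). Adjusted over the list alone, 6 rose. Log2 fold changes were 0.18 for Per1, 0.22 for Per2, 0.07 for Per3, 0.06 for Dbp and 0.29 for Ciart, and none of these passed over all genes. As a set the 10 genes passed with a median log2 fold change of 0.20 (camera, adjusted p = 6.99e-06), and all 10 were positive. That call was lost when the correlation was estimated (adjusted p = 0.14 with an estimated correlation). Among annotation terms, 3 of 2651 were over-represented among genes that rose and 0 among genes that fell. Circadian rhythm held 5 risen genes of 70 (Nr1d1, Nfil3, Arntl, Bhlhe40 and Npas2; adjusted p = 0.000705), circadian regulation of gene expression 4 of 48 (adjusted p = 0.00309), and nuclear body 5 of 218 (adjusted p = 0.0232). With camera both circadian terms passed (adjusted p = 1.48e-05 and 1.77e-05) and nuclear body did not (adjusted p = 0.986). The circadian counts include Nr1d1, itself targeted, and Bhlhe40 and Npas2, whose calls ended without any 1 V library. The terms were not tested again without single libraries.

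Over all 14438 genes tested, 43 rose and 17 fell in the r1r2V libraries. At an unadjusted p under 0.05 the counts were 571 and 524. The counts dropped to 19 or 20 higher and 7 or 8 lower when any V library was left out, and were 69 and 40 with DESeq2.

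The called genes were gathered on chromosome 14. It held 28 of the 60, of 515 genes tested there (Fisher's exact test, odds ratio 24.9, 95% interval 14.3 to 43.1, adjusted p over chromosomes 1.02e-23). With near-identical copies summed, it held 13 called of 494 tested (odds ratio 13.8, 95% interval 6.49 to 27.9, adjusted p over chromosomes 8.7e-09). Of the 28 called with copies kept apart, 16 started between 3.0 and 7.5 Mb, where 14 rose and 2 fell. Of those 16, 13 belonged to a family of 15 near-identical copies. Gm3500 (9.97-fold), LOC100861615 (6.80-fold), Gm3488 (5.75-fold) and Gm3383 (4.82-fold), of that family, rose, as did its neighbour Gm5795 (6.06-fold). D830030K20Rik, another copy, fell from 9.40 ± 1.23 to 1.23 ± 0.136 CPM (SD, n = 3 each). Gm3317, also of the family, had 233 counts over the V libraries and 0 over the r1r2V libraries, and was at least 78-fold lower against a floor of 3 counts over the group. Values of single copies are uncertain, and their summed count rose 3.63-fold (log2 fold change 1.86, adjusted p = 0.000166). Further along the chromosome, Ccnb1ip1 (16.9-fold) and Myh6, which encodes a cardiac myosin heavy chain (11.4-fold), rose. Plac9a and Plac9b, near-identical copies, fell, and so did 4930452B06Rik (log2 fold changes -1.95, -1.56 and -1.01), with the summed count of Plac9a and Plac9b changed by -1.73 (adjusted p = 0.0088).

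Chromosome 2 held 7 called genes, 6 of them starting between 100 and 130 Mb, and chromosome 11 held 6. Neither passed when tested against all other chromosomes, chromosome 14 among them (Fisher's exact test, odds ratios 1.54 and 1.29, adjusted p = 0.601 and 0.733). With near-identical copies summed, the odds ratios were 2.48 and 1.64 (adjusted p = 0.351 and 0.756). On chromosome 2, Fam227b rose 25.5-fold, from 0.0987 ± 0.0373 to 2.67 ± 0.391 CPM (SD, n = 3 each). Bub1b, which encodes a mitotic checkpoint kinase, fell from 3.69 ± 0.380 to 0.597 ± 0.403 CPM, and Ccdc3 from 9.01 ± 0.748 to 4.32 ± 0.322 CPM (SD, n = 3 each). On chromosome 11, Fkbp10 fell by 0.87 on the log2 scale. Elsewhere, Padi2, which encodes a peptidylarginine deiminase, fell from 70.0 ± 13.6 to 26.5 ± 3.44 CPM (SD, n = 3 each; log2 fold change -1.40, adjusted p = 0.00167). Eif3j2 rose 37.9-fold and Eno1b, with 8708 counts over the V libraries and 8 over the r1r2V libraries, changed by -10.05 on the log2 scale. Each has a near-identical copy, and the summed counts of Eif3j1 with Eif3j2 and of Eno1 with Eno1b did not pass (log2 fold changes -0.07 and -0.05, adjusted p = 0.818 and 0.896). Calls of Fkbp10, 4930452B06Rik, Bub1b, Ccdc3, Myh6, Plac9a and Plac9b ended when single libraries were left out, with adjusted p up to 0.274, 0.240, 0.0849, 0.0758, 0.0844, 0.103 and 0.064, and that of Myh6 also with limma-voom and on log2(FPKM + 1), and that of Fkbp10 with the filter of 1 CPM and on log2(FPKM + 0.1).

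**Figure D2:**
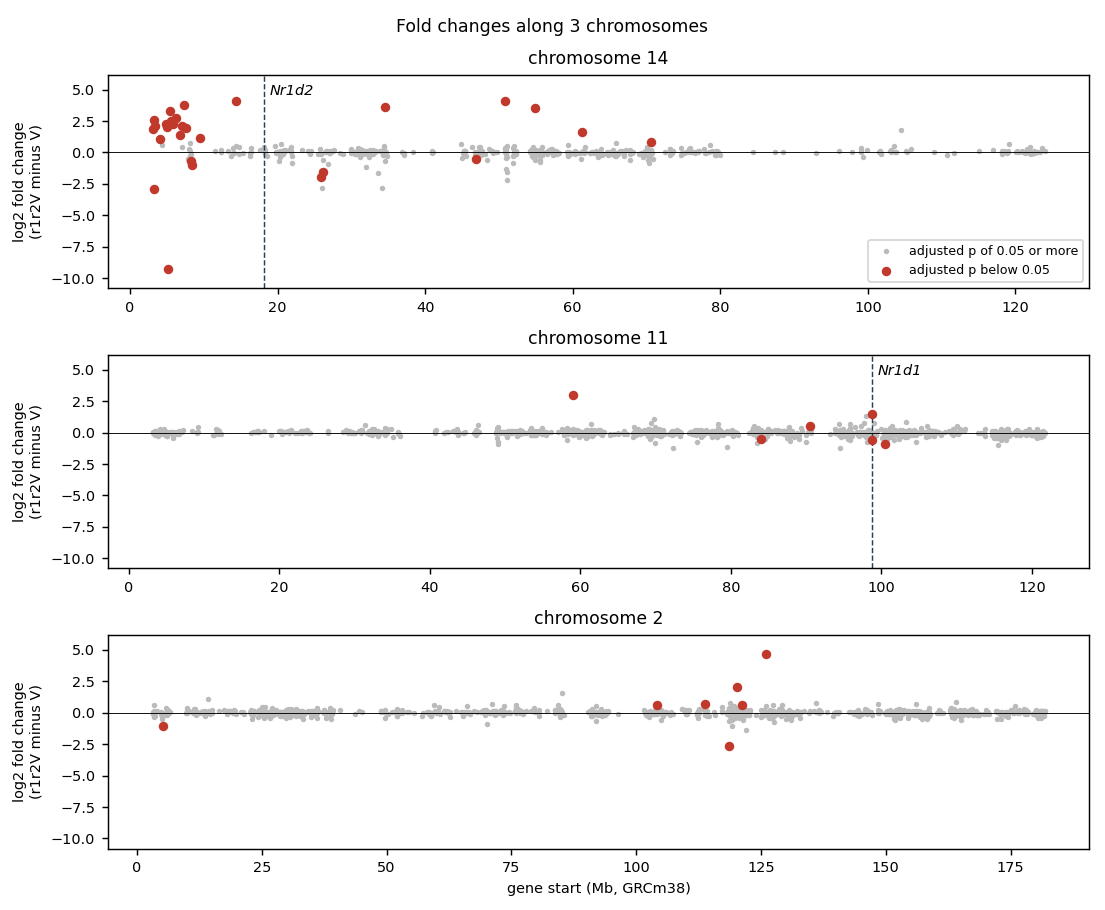
Log2 fold change (r1r2V minus V, vertical axis) of each tested gene against its start in Mb (GRCm38, horizontal axis) on chromosomes 14, 11 and 2, with called genes in red, other genes in grey and a dashed line at Nr1d2 or Nr1d1. Of the 28 called genes on chromosome 14, 16 lie between 3.0 and 7.5 Mb.

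Neuropeptide genes of the SCN did not pass the test. Of 21 measured genes of SCN peptides, receptors and signalling, 0 rose and 0 fell, and adjusted over the list alone 1 rose (Rgs16) and 1 fell (Avpr1a). Avp, the vasopressin gene, had 289 ± 62.1 CPM in V and 245 ± 122 CPM in r1r2V (SD, n = 3 each). Vip had 63.5 ± 19.3 and 44.6 ± 30.7 CPM, Grp 5.04 ± 0.421 and 4.75 ± 1.09 CPM, and Prok2 4.76 ± 2.54 and 11.4 ± 9.37 CPM (SD, n = 3 each). The wide spread in r1r2V included replicate 5, with 11.4 CPM of Vip and 1.75 CPM of Prok2. The set as a whole did not pass (camera, median log2 fold change -0.11, adjusted p = 0.346), nor did 10 SCN transcription factors (-0.12, adjusted p = 0.146). Of 25 genes of GABA synthesis, transport and reception, 0 rose and 0 fell (median 0.01, adjusted p = 0.950). The GABA-synthesising enzyme genes Gad1 and Gad2 had log2 fold changes of -0.04 and 0.04, and Slc32a1, the vesicular GABA transporter gene, -0.25 (adjusted p = 0.314).

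Immediate early genes, which neuronal activity induces, passed as a set at the preset correlation (camera, median log2 fold change 0.27, adjusted p = 0.000295, 13 of 18 positive). That call was lost when the correlation was estimated (adjusted p = 0.14 with an estimated correlation). The list also did not pass with fry (adjusted p = 0.141), which tests a list against no change and not against other genes. Over all genes 0 rose and 0 fell, and adjusted over the list alone 6 rose. Fosb had a log2 fold change of 0.91 (adjusted p = 0.0668) and Fos one of 0.04. Markers of meningeal fibroblasts, a cell type of the brain's coverings, also passed as a set (median 0.44, adjusted p = 0.0115), with 0 of 7 risen over all genes and 1 adjusted over the list alone. Over all 6 libraries that call was lost when the correlation was estimated (adjusted p = 0.70 with an estimated correlation). The means of their log2 CPM relative to the V mean were -0.15, 0.32 and 1.12 in r1r2V replicates 1, 4 and 5. Without replicate 5 the adjusted p of camera at the preset correlation was 0.93. None of the 4 sets that passed did so with an estimated correlation, and other divisions of the 6 libraries into groups of 3 gave up to 11 passing sets.

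The other lists did not pass. Heat- and cold-shock genes had a median of 0.13 (adjusted p = 0.0913), and adjusted over the list alone 4 rose and 2, Cirbp and Rbm3, fell. Microglia markers had a median of 0.11 (adjusted p = 0.0606), choroid plexus markers 0.16 (0.531) and markers of neighbouring hypothalamic neurons -0.15 (0.112). Genes repressed by REV-ERB in other tissues had a median of 0.01 (adjusted p = 0.532). Ion channels of SCN firing, glutamate synapse genes and pan-neuronal markers had medians of 0.01, 0.04 and -0.02 (adjusted p = 0.878, 0.878 and 0.565). Markers of astrocytes, oligodendrocytes, oligodendrocyte precursors and endothelial cells had medians of 0.00, -0.02, 0.02 and 0.03 (adjusted p = 0.950, 0.565, 0.878 and 0.928). Mural, ependymal and red blood cell markers had medians of -0.02, -0.05 and 0.03 (adjusted p = 0.928, 0.531 and 0.878). The mean was 0.01 for mural cells, where the set test also pointed up, and 0.01 for astrocytes, where it pointed down.

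**Figure D3:**
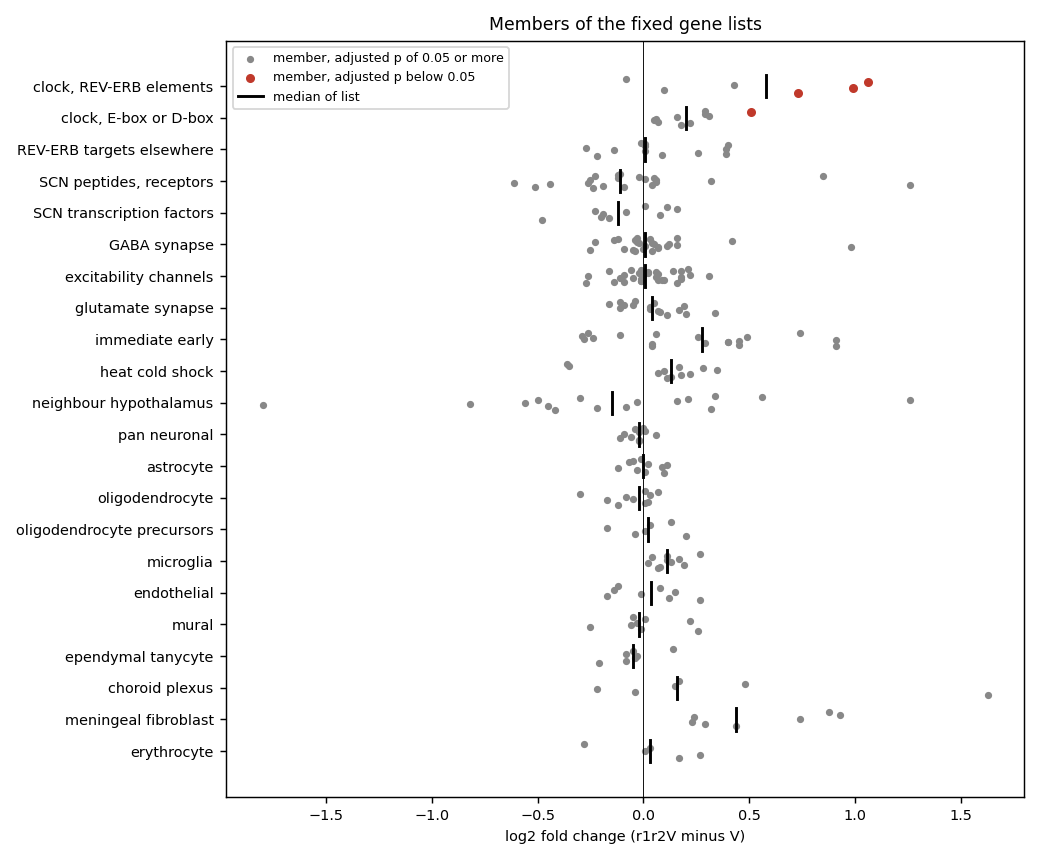
Log2 fold change (r1r2V minus V, horizontal axis) of each measured member of 22 gene lists (1 line each), with called members in red, others in grey and the list's median as a black bar. The called members are Arntl, Npas2 and Nfil3, of the clock genes with REV-ERB elements, and Bhlhe40, of those driven by E-boxes or D-boxes.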

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

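All settings here were chosen before the data were examined, except summing near-identical copies and leaving out chromosomes 2, 11 and 14, which were added after seeing the data. No paired analysis was possible because the groups share only replicate number 4. DESeq2 called 69 genes higher and 40 lower, and these 109 held all 60 called by edgeR, while limma-voom called 53, all among the 60. Without 1 library, 19 to 52 genes were higher and 7 to 24 lower, with 20 and 7 without V replicate 2, 20 and 8 without V replicate 3, and 19 and 7 without V replicate 4. With copies summed, 28 were higher and 12 lower, and without chromosomes 2, 11 and 14, 14 and 5, since fewer genes were then counted. Other scalings, FPKM, filters and thresholds gave 33 to 52 higher and 15 to 21 lower. Nr1d1 stayed past the threshold in every fit that left out 1 library (log2 fold change 1.37 to 1.58). Nr1d2 was 0.47 and past the threshold with DESeq2 and without a filter, and ran from 0.37 to 0.53 without 1 library. With this depth, spread and number of libraries together, 2% of simulated 1.2-fold and 52% of 1.5-fold changes were recovered. The simulated changes were in genes with a mean of at least 1 CPM, both groups were given the same spread, and depth alone was not varied. Of annotation terms, camera passed 6 higher and 2 lower.

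Genes near 0 changed sign without 1 library: Per2 (-0.02 to 0.37), Per3 (-0.03 to 0.12), Dbp (-0.01 to 0.12), Gad1 (-0.12 to 0.03), Gad2 (-0.07 to 0.12) and Grp (-0.29 to 0.03). With an estimated correlation the adjusted p was 0.14 for the REV-ERB element, E-box and immediate early lists and 0.70 for fibroblasts, and with fry 0.068, 0.095, 0.14 and 0.66. Heat- and cold-shock genes passed with DESeq2 (0.021), limma-voom (0.048) and log2(FPKM + 1) (0.048), and microglia with limma-voom (0.021) and log2(FPKM + 1) (0.0074). Direction turned for GABA synapse genes with DESeq2 (0.94) and for astrocytes with fry (0.99). Without 1 library, adjusted p ran from 3.4e-06 to 0.93 for fibroblasts (0.93 without r1r2V replicate 5), 0.019 to 0.40 for heat- and cold-shock genes and 0.0055 to 0.34 for microglia. It ran from 0.0023 to 0.98 for oligodendrocytes, 0.0067 to 0.90 for red blood cells, 0.034 to 1 for SCN peptides, 0.042 to 0.95 for SCN transcription factors and 0.042 to 0.22 for neighbouring neurons. For lists that changed direction without passing it ran from 0.62 to 0.92 (GABA synapse), 0.12 to 0.99 (ion channels), 0.49 to 0.92 (glutamate synapse), 0.066 to 0.98 (pan-neuronal), 0.29 to 0.99 (astrocytes), 0.33 to 0.99 (oligodendrocyte precursors), 0.42 to 1 (endothelial), 0.28 to 0.99 (mural) and 0.081 to 0.92 (ependymal). The cause was not tested where none is given.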

Other observations

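The tests of explanations for the 3 patterns were chosen after the result was seen, and the divisions of the libraries were planned. Genes outside the lists also differed, and Ndn, Scg5 and Fam107a were chosen after their values were seen. Ndn, an imprinted neuronal gene, rose from 852 ± 123 to 1590 ± 114 CPM (SD, n = 3 each; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00289), with all 3 r1r2V libraries above all 3 V libraries. Scg5, which encodes a chaperone of prohormone convertase, rose from 380 ± 3.79 to 632 ± 89.2 CPM (adjusted p = 0.00641). It starts at 113.8 Mb on chromosome 2, among the 6 called genes there between 100 and 130 Mb. Fam107a fell from 235 ± 11.3 to 149 ± 8.96 CPM (adjusted p = 0.00187). It starts at 8.3 Mb on chromosome 14, the chromosome on which called genes gathered. Rgs16, a G-protein signalling gene and a member of the SCN peptide and receptor list, was also chosen after its values were seen. It had 57.5, 53.7 and 56.1 CPM in V and 116, 114 and 71.8 CPM in r1r2V (log2 fold change 0.85, adjusted p = 0.0588), so it did not pass.

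Peptide genes of neighbouring hypothalamic neurons varied between libraries of one group. Pmch had 12.4, 213 and 23.3 CPM in V and 16.8, 1.67 and 581 CPM in r1r2V, and Pomc 5.42, 303 and 22.7 CPM in V and 23.7, 2.76 and 68.8 CPM in r1r2V. The second principal component (25.8% of variance) set r1r2V replicate 5 at -27.2, with the other libraries between -1.8 and 16.2.

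The first pattern is the gathering of called genes on chromosome 14, where Nr1d2 lies. Reads shared between near-identical copies are argued against as the whole source, since with copies summed the odds ratio was 13.8 (95% interval 6.49 to 27.9). Inherited DNA linked to the targeted locus is a candidate explanation. The 13 called genes or families lay at a median of 13.2 Mb from Nr1d2, against 37.3 Mb for the others tested there (1-sided permutation test, 100000 resamples, p = 0.0183). Distances of the called ones ran from 3.9 to 52.4 Mb, and the test treats genes as independent. Around Nr1d1 on chromosome 11, 4 called genes lay at a median of 11.5 Mb against 22 Mb (1-sided permutation test, p = 0.107). They include Thra, which overlaps Nr1d1 and whose reads there cannot be told apart from those of Nr1d1. A local effect of the knockout on neighbouring genes stays open and untested, and strain background beyond the label was not examined.

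The second pattern is the higher Nr1d1 level in the libraries labelled r1r2V. An exchange of the labels of the 2 groups would put genes with REV-ERB elements lower there, if loss of REV-ERB repression raises them. Their median log2 fold change was 0.58, but the list did not pass with an estimated correlation (camera, adjusted p = 0.14). The same rise is the basis of the hypothesis of lost repression given for the third pattern, so it is not separate support for that hypothesis. A larger share of SCN neurons is argued against by SCN peptide and receptor genes, whose mean log2 fold change was -0.03 with a standard error of 0.09 over 21 genes. Reads of Thra stay open as a source, because strand use was not given and the genes overlap by 1075 bp, where their reads cannot be told apart. Thra changed by -214 CPM (standard error 28.7) while Nr1d1 gained 108 CPM (standard error 15), so the size of the loss does not exclude it. Gene totals do not place reads, so how much of the gain lies in the overlap is not known. Loss of self-repression with transcripts kept from the exons left in place may also raise Nr1d1, and it stays open and untested because totals cover all exons.

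The third pattern is that 2 lists of clock genes, taken to be of opposite phase, both had positive mean changes. Only Bhlhe40 of the 10 E-box or D-box genes passed over all genes. If genes with REV-ERB elements and those driven by E-boxes are of opposite phase here, a difference in sampling time would move them apart. The single time window sampled cannot show their phases. On that assumption, a difference in sampling time is argued against as the whole source. Such a difference combined with an effect of the knockout was not tested. The mean log2 fold changes of these lists were 0.54 (standard error 0.19 over 6 genes) and 0.22 (standard error 0.05 over 10 genes). Such errors treat genes as independent and leave out the spread between libraries. Relative to the V mean, the first list averaged 0.63, 0.6 and 0.36 in r1r2V replicates 1, 4 and 5. The second averaged 0.3, 0.2 and 0.14, and both lay between -0.05 and 0.04 in the V libraries. The adjusted p of each of the 2 lists was 0.14 with an estimated correlation. Whether differences in dissection between libraries contribute to this pattern was not tested and stays open. SCN peptide and receptor genes averaged -0.03, 0.1 and -0.35 in r1r2V replicates 1, 4 and 5, and meningeal fibroblast markers -0.15, 0.32 and 1.12. A hypothesis that remains is loss of REV-ERB repression, which may raise the first list and was not separated from other effects of the knockout.

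The 10 divisions of the 6 libraries into groups of 3 are too few for a share under 0.05. The real division gave 43 genes higher and 17 lower, and the highest count of the other divisions in either direction was 0, so 1 of 10 divisions reached each count. For gene lists the real division passed 4 and the highest of the others 11, and 8 of 10 divisions passed 4 or more, so the number of passing lists does not set the genotype apart from other divisions. Whether this comes from the libraries or from the preset correlation of 0.01 was not tested, and the correlations estimated within lists reached 0.9.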
